A study of Mus musculus with 24 samples.

How the data were processed

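The study measured total RNA from cultured bone marrow-derived macrophages on Affymetrix expression arrays. Per the labels, cells came from 3 male mice per genotype, the cells of each donor were split between medium and medium with flagellin, 3 wells were pooled per RNA sample, and the experiment was done in triplicate. The labels number the arrays of a group 1 to 3 but do not tie a number to a mouse or say that equal numbers share a donor, so p-values measure the spread between these arrays. The authors deposited 1 table of log2 values per probe set, with 45037 probe sets and 24 arrays. How the authors computed and normalized these log2 values is not given in the sources used here. Array medians lay between 6.548 and 6.6391, within the tolerance of 0.1 set before the data were examined, so the values were used as deposited, with no further normalization and no filter on low values. No pair of arrays held identical values.

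Of the probe sets, 4 had no values and 45033 were used. Gene symbols came from a table that lists 35877 of the probe sets; 34945 had 1 symbol, 932 had several and were left out, and 9160 had none. Each of 18193 genes was represented by its probe set with the highest mean over all arrays, and 9010 genes had more than 1 probe set. Chromosomes and gene order came from a RefSeq gene table of GRCm38.p6, in which 18032 of the genes were found through their Entrez number; no coordinates were used. A strain's sequence variants under a probe can change its signal. For this the other probe sets of each gene selected for naming were examined: of 482 changes, 216 had another probe set, 29 of these had one of opposite sign, and 9 had one of opposite sign at an unadjusted p under 0.05.

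Differences were tested with limma 3.58.1 in R 4.3.3. A linear model of the 8 group means was fitted to all 24 arrays (16 residual degrees of freedom), followed by eBayes with default settings, which estimated 3.99 prior degrees of freedom. The 16 contrasts were the flagellin change in each strain, C3Bir against B6, BC-R3 against B6 and CB-R1 against C3Bir in each condition, the Cdcs1 allele effect, and differences of the flagellin change for the same 3 pairs, by background and by allele. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and genes with an adjusted p under 0.05 were called. Fisher's exact test compared the share of called genes on each chromosome, adjusted over 20 chromosomes. A total of 27 gene lists was fixed before the data were examined, with 482 distinct genes, of which 438 were measured and 44 were not analysed here: inflammatory cytokines, chemokines, NF-kB pathway and feedback, interferon-stimulated genes, chromosome 3 guanylate-binding proteins, pattern recognition, antigen presentation, macrophage effectors, alternative activation, macrophage identity, immediate early genes, sterol synthesis and LXR targets, glycolysis and hypoxia, NRF2 and antioxidant genes, lysosome and cathepsins, proliferation, genes near Cdcs1, and markers of neutrophils, B cells, T and NK cells, dendritic cells, stromal cells, osteoclasts, mast cells and basophils, eosinophils, erythroid cells and megakaryocytes, and endothelial cells and adipocytes. Each list was tested with limma's camera with a preset correlation of 0.01, adjusted over the 27 lists, with an estimated correlation as an alternative. With the preset correlation 142 of the list tests were called over the 16 contrasts, and with an estimated correlation 0 were, with 17 at an unadjusted p under 0.05 and a lowest adjusted p of 0.16.

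Genes to be named were chosen by a rule fixed before the data were examined. In a comparison of a pair of groups these were the 10 largest rises and the 10 largest falls among called genes whose 3 arrays per group did not overlap. In the allele effect and the differences of the flagellin change they were the 5 largest in each direction. Up to 4 called members per list with the largest change were added, and a fixed set of genes of innate sensing and of the locus, among them Il10, Tlr5, Naip5, Tnf, Il6, Il1b, Il12b, Nos2, Ccl5 and Cxcl10. Of these the text names mainly genes whose calls did not depend on a single array. That preference, and the choice of which lists to describe in which comparison, were made after the results had been seen.

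Alternatives fixed in advance were quantile normalization, median centring, a filter on low values, all probe sets, the mean of a gene's probe sets, eBayes with trend and robust options, a fit of the compared arrays alone, 3 forms of a block by replicate number, a 2-fold threshold, and leaving out each array in turn. The fry test was fixed in advance as a second test of the lists. Chosen after the data had been seen were 2 exclusions of arrays. The first left aside unstimulated arrays 2 and 3 of B6 and C3Bir, the 4 arrays with the highest cytokine mean, called the 4 high arrays in the text; the second left aside unstimulated array 1 of B6, C3Bir and BC-R3. Both were picked from expression values, so their counts show only how far a result rests on those arrays. The pipeline was tested on simulated data with 200 changed genes among 18193. For the B6 contrast it recovered 89% of genes changed 1.5-fold and 95% of those changed 2-fold, with 9 and 6 false calls, and for the allele effect 98% and 98.5%, with 11 and 13 false calls. The simulated noise was independent between genes and had the same SD in all 8 groups. The real arrays had deviations shared by many genes and unequal spread between groups, so these rates need not hold for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.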

Results

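Gene expression was measured on 24 arrays of RNA from bone marrow-derived macrophages of male mice described as deficient in Il10, the gene of an anti-inflammatory cytokine. Cdcs1 is a colitis susceptibility locus on chromosome 3. The 4 strains were the colitis-susceptible C3Bir, the colitis-resistant B6 and a pair of reciprocal congenic strains. BC-R3 had the B6 background with the Cdcs1 region of C3Bir, and CB-R1 had the C3Bir background with a long B6 segment of chromosome 3 that contains Cdcs1. Cells were cultured for 6 days, and those labelled flagellin received 1 µg/mL of a flagellin of commensal gut bacteria for the last 4 h. Each of the 8 groups had 3 arrays, numbered 1 to 3, and this number limits the precision. Median log2 values per array ranged from 6.55 to 6.64, and arrays of 1 group correlated at 0.987 to 0.998. The values carry no call of detection, so against a group whose mean lies near or below the lower quartile of the arrays, 5.29 to 5.42, differences are in signal and no fold is given. The Il10 probe set gave 6.36 to 8.70 on the 24 arrays, and whether it lies in the disrupted part of the gene was not examined.

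Inflammatory gene levels varied among the arrays labelled unstimulated. The mean log2 value over 19 inflammatory cytokine genes, among them Tnf, Il1b and Il6, was 9.93 and 10.02 on B6 unstimulated arrays 2 and 3. It was 8.74 and 8.64 on C3Bir unstimulated arrays 2 and 3. The other 8 arrays labelled unstimulated had 7.45 to 8.12, and the 12 labelled flagellin had 7.61 to 7.96. The mean over 30 interferon-stimulated genes was 12.02 and 12.04 on B6 unstimulated arrays 2 and 3, against 9.03 to 11.19 on the other 22 arrays. All groups below are named by their labels.

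**Figure D1:**
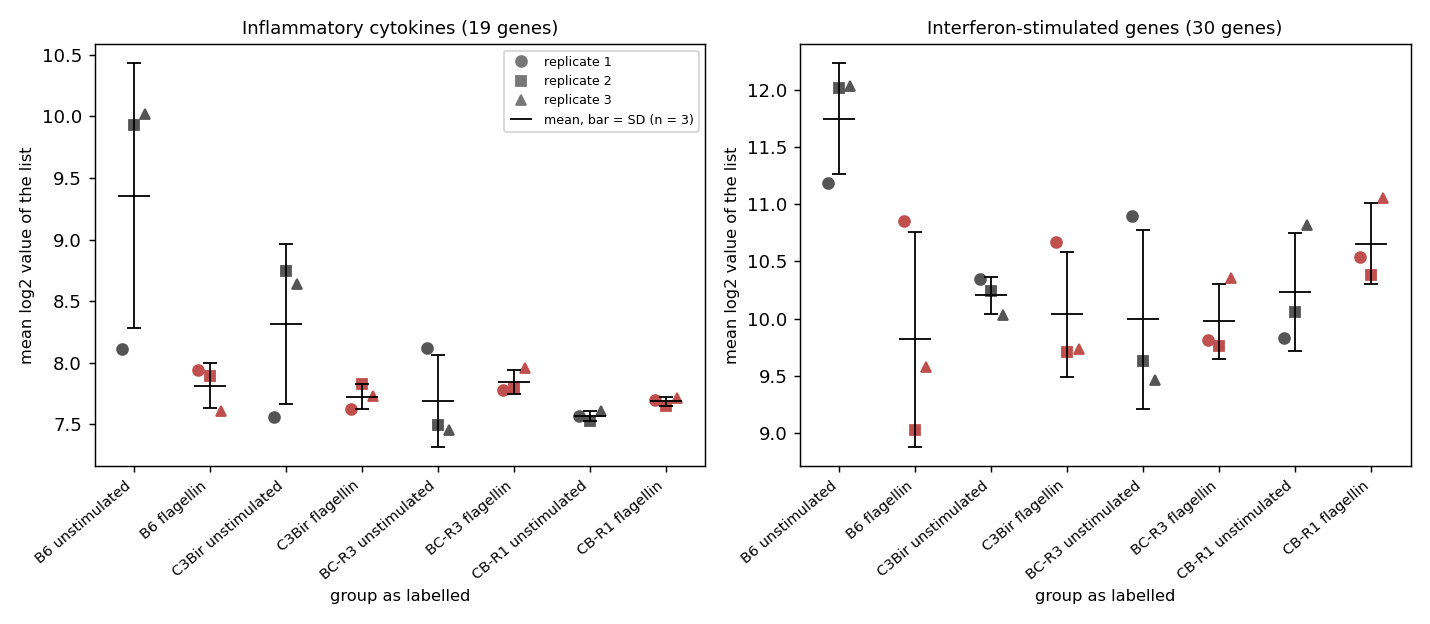
Mean log2 value over the 19 inflammatory cytokine genes and over the 30 interferon-stimulated genes on each of the 24 arrays (y axis), by labelled group (x axis), with points for replicates 1 to 3 and the group mean with its SD (n = 3). B6 unstimulated arrays 2 and 3 are the highest in both panels, and on the cytokine list C3Bir unstimulated arrays 2 and 3 come next at 8.74 and 8.64.

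The first comparison asked what flagellin changed in B6 macrophages. Cytokine, chemokine and interferon-induced genes were lower on the arrays labelled flagellin. Il6, a pro-inflammatory cytokine, was lower, at 4.07 ± 0.22, below the lower quartile, against 8.94 ± 3.68 on the arrays labelled unstimulated (mean log2 value ± SD, n = 3). Cxcl10, an interferon-induced T cell chemokine, was 11.4-fold lower. Mx1, an antiviral GTPase, fell by 3.49 ± 0.77 on the log2 scale (± SE), and Oasl1, of the oligoadenylate synthetase family, fell by 3.38 ± 0.71. Gpr183, an oxysterol receptor, was 4.58-fold higher. Lpar6, a lysophosphatidic acid receptor, Arrdc3, an arrestin-domain protein, and Dbp, a transcription factor of the circadian output, rose by 2.13, 1.75 and 1.63 on the log2 scale. The largest adjusted p of these 8 genes was 0.00808. In each the 3 arrays of one condition lay above the 3 of the other. The naming rule required this, so it adds no evidence for these genes, and chance alone gives it for 10% of genes.

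By gene list, 29 of 30 interferon-stimulated genes fell in B6, and adjusted over the list alone also 29 fell and 1 rose (camera adjusted p = 1.02e-15, adjusted p = 0.594 with an estimated correlation). Of 19 inflammatory cytokine genes 12 fell and 7 did not pass, and adjusted over the list alone 14 fell (camera adjusted p = 1.40e-07, adjusted p = 0.594 with an estimated correlation). Of 21 chemokine genes 11 fell, with Cxcl9 at -2.77 ± 0.38 and Ccl12 at -3.28 ± 0.56 (log2 ± SE), and adjusted over the list alone 13 fell and 1 rose (camera adjusted p = 2.30e-06, adjusted p = 0.594 with an estimated correlation). The NF-kB list had 7 of 21 genes lower, 9 adjusted over the list alone, among them the phosphatase gene Dusp2 at -1.32 ± 0.28 (camera adjusted p = 2.04e-04, adjusted p = 0.640 with an estimated correlation). In the list of antigen presentation 6 of 20 genes fell, 6 adjusted over the list alone, including the peptide transporter subunit Tap1 at -1.72 ± 0.30 (camera adjusted p = 0.0256, adjusted p = 0.640 with an estimated correlation). Of 22 macrophage effector genes 4 fell, 4 adjusted over the list alone, including Nos2, the inducible nitric oxide synthase, at -1.36 ± 0.28 (camera adjusted p = 0.00314, adjusted p = 0.640 with an estimated correlation). Of 4 guanylate-binding protein genes of chromosome 3, 3 fell, 3 adjusted over the list alone, with Gbp7 at -2.84 ± 0.59 (camera adjusted p = 0.0254, adjusted p = 0.640 with an estimated correlation). The pattern recognition list had 6 genes lower and 3 higher of 26, with 8 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.280, adjusted p = 0.640 with an estimated correlation). Its members Nod1 and Tlr3 fell by 1.69 and 1.39, while Tlr13, a receptor for bacterial ribosomal RNA, rose by 0.88. Il10 stood at -1.19 ± 0.27 (adjusted p 0.00606, or 0.0531 without B6 unstimulated array 2). Tlr5, the cell surface receptor for flagellin, stood at -0.08 ± 0.10 with an adjusted p of 0.573. Lysosomal genes were higher, 8 of 16, with 1 lower and 8 higher adjusted over the list alone (camera adjusted p = 0.0187, adjusted p = 0.640 with an estimated correlation). Sterol genes were also higher, 5 of 17 against 1 lower, with 1 lower and 6 higher adjusted over the list alone, including Scd2 and Sqle, enzymes of lipid and sterol synthesis, at 1.12 ± 0.23 and 0.55 ± 0.11 (camera adjusted p = 0.0443, adjusted p = 0.640 with an estimated correlation). The 14 markers of stromal cells had a median of -0.74, with 0 passing in limma over all genes, 0 adjusted over the list alone (camera adjusted p = 0.0204, adjusted p = 0.640 with an estimated correlation). In the same contrast 3 of 11 mast cell markers were lower, 4 adjusted over the list alone (camera adjusted p = 0.00250, adjusted p = 0.594 with an estimated correlation).

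In total 4068 of 18193 genes differed between the conditions in B6 by limma, 2342 higher and 1726 lower with flagellin. Of these 302 differed at least 2-fold, 86 higher and 216 lower. The count was 1039 without B6 unstimulated array 2, 985 without B6 unstimulated array 3 and 2214 without B6 flagellin array 1. Of the 87 genes selected for naming 29 passed whichever array was left out. They include each gene named above as higher or lower except Il10, since the text preferred such genes. A limma fit of these 6 arrays alone gave 0 genes, with 4524 at an unadjusted p under 0.05. The p-values of the main fit can be too small here, since its spread is shared with groups that varied less than B6 unstimulated. Leaving aside the 4 high arrays, unstimulated arrays 2 and 3 of B6 and C3Bir, also gave 0 in limma, with 1293 at an unadjusted p under 0.05. In that second fit the medians of the interferon-stimulated, chemokine and cytokine lists were -1.22, -0.43 and -0.14. Leaving aside instead unstimulated array 1 of B6, C3Bir and BC-R3, the 3 arrays apart, gave 6282 genes; both sets of arrays were picked from their values, and removing arrays far from their group lowers the estimated spread.

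In the other 3 strains no single gene passed between the conditions. Limma called 0 genes in C3Bir, BC-R3 and CB-R1, with 1432, 1584 and 517 genes at an unadjusted p under 0.05 and lowest adjusted p values of 0.624, 0.0800 and 1.000. Il12b, the gene of the subunit shared by interleukins 12 and 23, stood at 5.88 ± 0.16 with flagellin against 8.21 ± 2.27 without in C3Bir (SD, n = 3, limma adjusted p 0.624), and in CB-R1 at 5.73 ± 0.15 against 5.61 ± 0.11. Il1b, the gene of interleukin 1 beta, differed by -1.71 ± 0.78 in C3Bir, 0.89 ± 0.78 in BC-R3 and 0.93 ± 0.78 in CB-R1 (log2 ± SE), with adjusted p values of 0.624, 0.817 and 1.000. Tlr5 differed by -0.20 ± 0.10, -0.33 ± 0.10 and -0.10 ± 0.10, with adjusted p values of 0.628, 0.258 and 1.000. As a set, the 21 NF-kB genes lay lower with flagellin in C3Bir, with a median of -0.43 (camera adjusted p = 4.24e-05, adjusted p = 0.781 with an estimated correlation). They lay higher in BC-R3, with 0.37 (camera adjusted p = 3.48e-04, adjusted p = 0.928 with an estimated correlation), and in CB-R1, with 0.30 (camera adjusted p = 0.00183, adjusted p = 0.804 with an estimated correlation). In limma 0 members passed in any of the 3 strains, 0 also adjusted over the list alone. The interferon-stimulated genes had a median of 0.34 in CB-R1 (camera adjusted p = 2.45e-05, adjusted p = 0.801 with an estimated correlation), again with 0 members passing by either adjustment. The stromal markers had 0.53 in BC-R3, likewise with 0 by either adjustment (camera adjusted p = 3.48e-04, adjusted p = 0.928 with an estimated correlation). Without C3Bir unstimulated array 1 the count in C3Bir was 93, and without BC-R3 unstimulated array 1 the count in BC-R3 was 213. Without the 3 arrays apart the counts in C3Bir, BC-R3 and CB-R1 were 1234, 905 and 0, the last with 771 genes at an unadjusted p below 0.05 by limma. In BC-R3 it was also 6 from the mean of a gene's probe sets and 14 with same-numbered arrays as a random block.

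Whether strains differed in this change was tested on the differences themselves. Il6, Il1b and Ccl5, all lower with flagellin in B6, had changes higher in BC-R3 than in B6 by 4.56 ± 1.40, 3.80 ± 1.10 and 3.32 ± 1.05 (log2 ± SE). Gpr183, the endocannabinoid receptor gene Cnr2 and Arrdc3 had changes lower in BC-R3 by 2.10, 2.29 and 2.03. Of 30 interferon-stimulated genes 15 had a higher change in BC-R3, and adjusted over the list alone 28 did and 1 had a lower one (camera adjusted p = 9.15e-12, adjusted p = 0.524 with an estimated correlation). The cytokine list had 7 of 19 higher, 16 adjusted over the list alone (camera adjusted p = 4.30e-07, adjusted p = 0.524 with an estimated correlation). The lysosomal list had 7 of 16 lower, 11 adjusted over the list alone (camera adjusted p = 9.39e-06, adjusted p = 0.524 with an estimated correlation). The stromal markers had a median difference of 1.25, with 1 of 14 higher and 0 adjusted over the list alone (camera adjusted p = 2.87e-04, adjusted p = 0.524 with an estimated correlation). Together 1917 genes differed in their change between BC-R3 and B6, 757 with a higher and 1160 with a lower change in BC-R3. Limma called 0 genes for C3Bir against B6, for CB-R1 against C3Bir, by genetic background and by Cdcs1 allele, with 2433, 894, 1082 and 1649 genes at an unadjusted p under 0.05. The count of 1917 became 4231, 95 and 107 without B6 unstimulated array 1, 2 or 3. It was 1071 and 803 without B6 flagellin array 1 or 3. Leaving out BC-R3 unstimulated array 1, 2 or 3 gave 3885, 140 and 40, and leaving out BC-R3 flagellin array 2 or 3 gave 600 and 232. After quantile normalization it was 1125, with the balance turned to 615 higher and 510 lower, and after median centring 587 higher and 1533 lower. A limma fit of these 12 arrays alone gave 0, with 4465 at an unadjusted p under 0.05, and leaving aside the 4 high arrays also gave 0, with 1737. In limma 0 of its 66 genes selected for naming passed whichever array was left out. For C3Bir against B6 the count was 1373 without B6 unstimulated array 1, 80 and 3 without B6 flagellin array 1 or 2 and 8 without C3Bir unstimulated array 1. For CB-R1 against C3Bir it was 4 without C3Bir unstimulated array 1. Without the 3 arrays apart the differences gave 1495 genes for C3Bir against B6, 5669 for BC-R3 against B6, 810 for CB-R1 against C3Bir, 379 by background and 1006 by allele. Leaving out single arrays, by background it was 270 without B6 unstimulated array 1 and 2 without B6 flagellin array 1. By allele it was 217 without B6 unstimulated array 1 and 1 without B6 flagellin array 2.

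The comparison of the parental strains asked how macrophages of the susceptible C3Bir differ from those of the resistant B6. Ifi202b, an interferon-inducible DNA-binding protein, was higher in C3Bir by 5.34 ± 0.23 on the arrays labelled unstimulated and by 5.52 ± 0.23 on those labelled flagellin (log2 ± SE). Ifi44l, an interferon-induced gene, was higher by 4.87 ± 0.34 and 4.92 ± 0.34, Gbp2b, an interferon-inducible GTPase, by 5.12 ± 0.57 and 4.08 ± 0.57, and Hal, histidine ammonia-lyase, by 4.05 ± 0.31 and 4.81 ± 0.31. Lower in C3Bir were Rpgrip1, of the photoreceptor cilium, at -3.78 ± 0.11, Cd5l, a secreted macrophage protein, at -4.07 ± 0.24, Ppbp, the platelet basic protein, at -3.36 ± 0.19 and Tlr1, which pairs with Tlr2 to detect lipopeptides, at -3.27 ± 0.50, all on the arrays labelled flagellin. The class I histocompatibility gene H2-D1 was lower at -2.58 ± 0.08 there, but of its 8 other probe sets 5 had the opposite sign, 4 of them at an unadjusted p under 0.05. Of the 3 other probe sets of Rpgrip1 1 had the opposite sign there, and of the 2 of Ifi44l 0 had. Ifi202b, Gbp2b, Hal, Cd5l, Ppbp and Tlr1 had no other probe set, so for them variants under the probes and expression cannot be told apart. The 9 genes had adjusted p values of at most 2.02e-04, and their 3 arrays per strain did not overlap, as the naming rule required. Genes that passed whichever array was left out were preferred for naming, and each of the 9 did. So did 60 of the 91 genes selected for naming on the arrays labelled unstimulated and 41 of the 63 on those labelled flagellin.

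By gene list, on the arrays labelled unstimulated 22 of 30 interferon-stimulated genes were lower in C3Bir, 28 adjusted over the list alone (camera adjusted p = 3.38e-13, adjusted p = 0.512 with an estimated correlation). There 10 of 21 chemokine genes were lower and 1 higher, with 13 lower and 2 higher adjusted over the list alone (camera adjusted p = 6.71e-05, adjusted p = 0.512 with an estimated correlation). Cxcl10 stood at -4.43 ± 0.84. With flagellin 0 interferon-stimulated genes were lower and 0 higher in limma, with 0 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.365, adjusted p = 0.929 with an estimated correlation). Likewise 2 chemokine genes were lower and 1 higher, with 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.134, adjusted p = 0.818 with an estimated correlation). Genes of the NRF2 and antioxidant list were lower on the arrays labelled flagellin, 3 of 14, or 5 adjusted over the list alone (camera adjusted p = 4.16e-04, adjusted p = 0.730 with an estimated correlation). The activity of the factor NRF2 was not tested. Cat, catalase, stood at -1.31 ± 0.10 and Gclm, of glutathione synthesis, at -1.18 ± 0.20. Antigen presentation genes were lower there too, 4 of 20 against 1 higher, with 4 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00746, adjusted p = 0.818 with an estimated correlation). The class II gene H2-Eb1 stood at -1.24 ± 0.25. In the macrophage identity list 3 genes were lower and 2 higher of 23, with 3 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.152, adjusted p = 0.818 with an estimated correlation). The complement genes C1qb and C1qc stood at -1.17 ± 0.20 and -0.71 ± 0.15. Among markers of other cells on the arrays labelled flagellin, 3 of 10 erythroid and megakaryocyte genes were lower, Ppbp among them, 4 adjusted over the list alone (camera adjusted p = 4.16e-04, adjusted p = 0.730 with an estimated correlation). Neutrophil genes had a median of 0.47 there, with 0 passing by either adjustment (camera adjusted p = 0.0158, adjusted p = 0.818 with an estimated correlation), stromal genes -0.38, also with 0 (camera adjusted p = 0.152, adjusted p = 0.825 with an estimated correlation). Of 8 endothelial and adipocyte genes 1 was higher and 1 lower, with 1 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.999, adjusted p = 0.999 with an estimated correlation). Glycolytic and hypoxia genes were lower on the arrays labelled unstimulated, 7 of 16, or 8 adjusted over the list alone (camera adjusted p = 1.33e-04, adjusted p = 0.512 with an estimated correlation). Among markers of other cells on those arrays, 3 of 14 stromal genes were lower in C3Bir, 10 adjusted over the list alone (camera adjusted p = 7.52e-05, adjusted p = 0.512 with an estimated correlation). Erythroid and megakaryocyte genes were lower in 4 of 10, 4 adjusted over the list alone (camera adjusted p = 2.27e-04, adjusted p = 0.512 with an estimated correlation). Neutrophil genes were higher in 2 of 13, 3 adjusted over the list alone (camera adjusted p = 0.00513, adjusted p = 0.512 with an estimated correlation).

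Between C3Bir and B6 3046 genes differed on the arrays labelled unstimulated, 1899 higher and 1147 lower in C3Bir, and 1207 on those labelled flagellin, 674 higher and 533 lower. Median centring turned the latter balance to 517 higher and 619 lower. Genes of chromosome 4 made up 98 of those on the arrays labelled flagellin, with an odds ratio of 1.42 (Fisher's exact test, two-sided, adjusted p 0.0407 over 20 chromosomes). The first count was 1633 and 1582 without B6 unstimulated array 2 or 3, 1104 in a fit of the 6 arrays alone, 255 without the 4 high arrays and 3922 without the 3 arrays apart. The second was 790 and 785 without C3Bir flagellin array 2 or 3, 665 in a fit of the 6 arrays alone and 2030 without the 3 arrays apart.

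**Figure D2:**
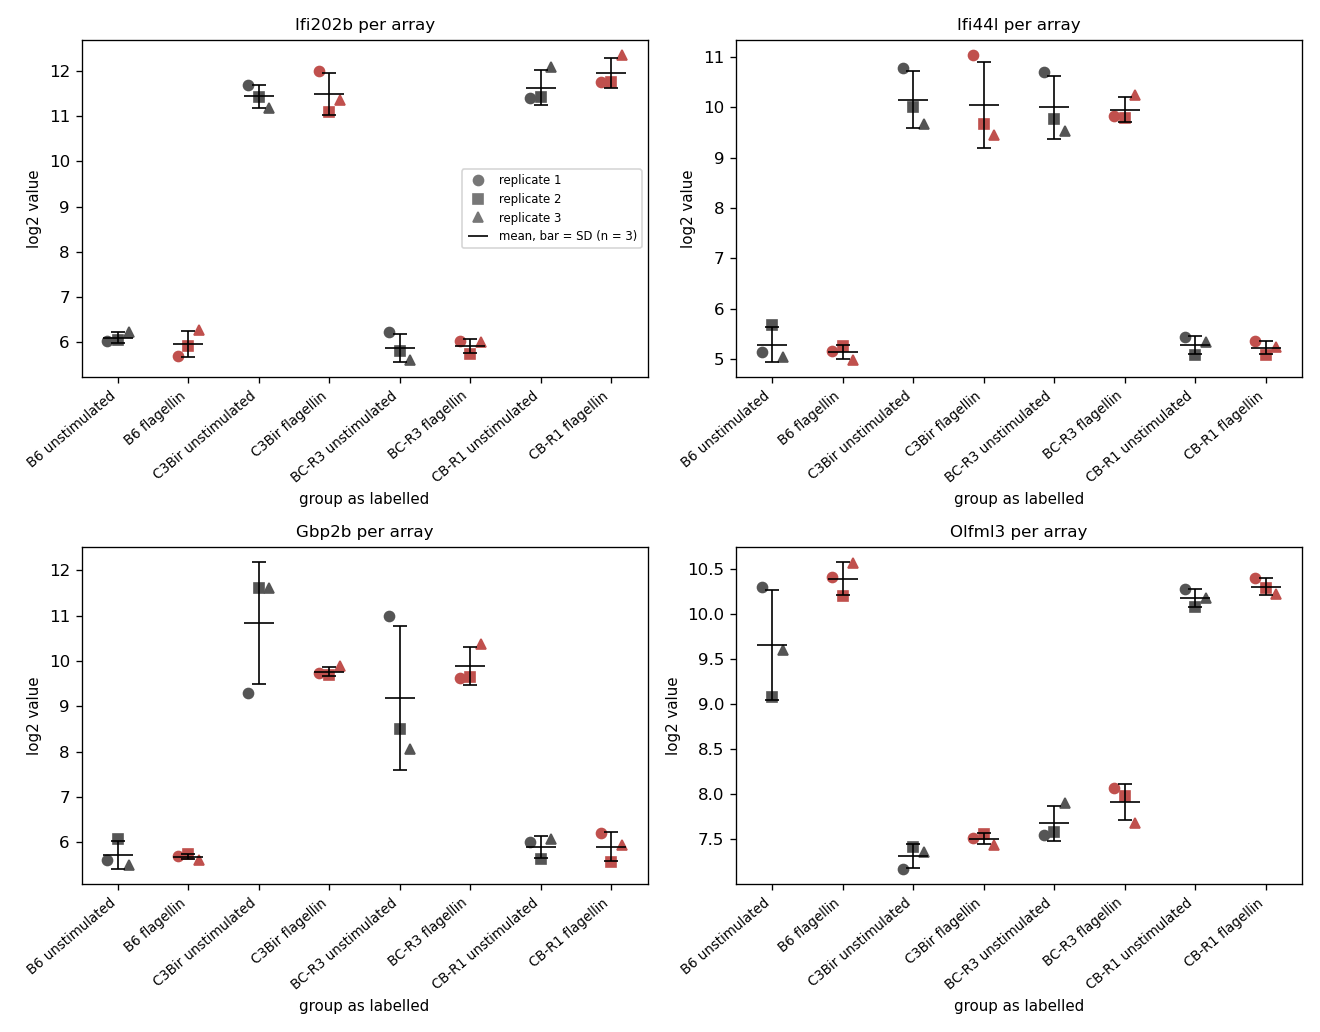
Log2 values of Ifi202b, Ifi44l, Gbp2b and Olfml3 on each of the 24 arrays (y axis), by labelled group (x axis), with points for replicates 1 to 3 and the group mean with its SD (n = 3). Ifi202b follows the genetic background, while Ifi44l, Gbp2b and Olfml3 follow the origin of the Cdcs1 region, with Olfml3 at 7.51 ± 0.06 in C3Bir and 10.39 ± 0.18 in B6 on the arrays labelled flagellin.

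BC-R3 was set against B6 to see what the C3Bir form of the Cdcs1 region changes on the B6 background. On the arrays labelled flagellin 3 genes differed, all on chromosome 3: Ifi44l stood at 9.96 ± 0.26 in BC-R3 against 5.13 ± 0.14 in B6, Gbp2b at 9.89 ± 0.42 against 5.68 ± 0.06, and Olfml3, a secreted olfactomedin-like protein, at 7.91 ± 0.20 against 10.39 ± 0.18 (SD, n = 3, limma adjusted p 1.09e-07, 0.00218 and 3.13e-07). On the arrays labelled unstimulated Ifi44l and Gbp2b were higher by 4.71 ± 0.34 and 3.46 ± 0.57 (log2 ± SE), and inflammatory genes were lower. Il6 stood at -4.69 ± 0.99, Tnf at -2.97 ± 0.63, Cxcl10 at -3.56 ± 0.84 and Cd40, a costimulatory receptor, at -3.79 ± 0.78. The probe set of the anti-inflammatory Il10 was also lower, at -1.29 ± 0.27. These SEs use the spread shared over all 8 groups. The cytokine mean ranged from 8.12 to 10.02 in B6 and from 7.45 to 8.12 in BC-R3, with array 1 at 8.12 in both. Naip5, an intracellular sensor of flagellin, was higher by 1.03 ± 0.18. Higher genes also included Gpr183 by 2.06 ± 0.38 and Fli1, a transcription factor, by 1.87 ± 0.35. Of 19 cytokine genes 16 were lower, 17 adjusted over the list alone (camera adjusted p = 1.59e-07, adjusted p = 0.576 with an estimated correlation). Among 21 NF-kB genes 18 were lower, with 20 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.59e-07, adjusted p = 0.576 with an estimated correlation). Of 30 interferon-stimulated genes 28 were lower and 1 higher, with 29 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.29e-11, adjusted p = 0.576 with an estimated correlation). Among 16 lysosomal genes 11 were higher and 1 lower, with 1 lower and 12 higher adjusted over the list alone (camera adjusted p = 9.64e-05, adjusted p = 0.576 with an estimated correlation). Stromal markers were lower in 5 of 14, 10 adjusted over the list alone (camera adjusted p = 4.09e-04, adjusted p = 0.576 with an estimated correlation). On the arrays labelled flagellin the proliferation list had a median of 0.16 with 0 members passing by either adjustment (camera adjusted p = 2.02e-05, adjusted p = 0.898 with an estimated correlation).

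In total 5513 genes differed between BC-R3 and B6 on the arrays labelled unstimulated, 3194 higher and 2319 lower in BC-R3. The count was 2984 and 2894 without B6 unstimulated array 2 or 3 and 3281 and 2757 without BC-R3 unstimulated array 2 or 3. Of the 101 genes selected for naming 61 passed whichever array was left out. The genes named above are among these 61, since the text preferred such genes. In a limma fit of the 6 arrays alone the count was 7, with 6298 at an unadjusted p under 0.05. It was 3 without the 4 high arrays, where the medians of the interferon-stimulated, chemokine and cytokine lists were -1.05, -0.67 and -0.19, and 7574 without the 3 arrays apart.

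CB-R1 was set against C3Bir to see what the B6 segment changes on the C3Bir background. In the arrays labelled flagellin Olfml3, Ppbp and Mcoln3, an endolysosomal cation channel, were higher in CB-R1 by 2.80 ± 0.19, 1.49 ± 0.19 and 1.44 ± 0.13 (log2 ± SE). Ifi44l stood at 5.23 ± 0.14 in CB-R1 against 10.06 ± 0.85 in C3Bir and Gbp2b at 5.90 ± 0.32 against 9.76 ± 0.10 (SD, n = 3). The other 5 of the 10 genes were Chil3, a chitinase-like protein made by alternatively activated macrophages, Adgrg3, Pxylp1, Gstp1 and H2bc18, higher by 1.37, 0.73, 0.67, 0.51 and 0.48 on the log2 scale. In the arrays labelled unstimulated Olfml3 and Mcoln3 were higher by 2.86 ± 0.19 and 1.74 ± 0.13 (log2 ± SE), and Ifi44l and Gbp2b stood at -4.87 ± 0.34 and -4.94 ± 0.57. There 11 of 23 proliferation genes were higher in CB-R1, 22 adjusted over the list alone (camera adjusted p = 2.66e-20, adjusted p = 0.199 with an estimated correlation). Examples were Rrm2, of nucleotide synthesis, at 1.20 ± 0.21 and Mcm5, of the replicative helicase, at 0.94 ± 0.17. Genes of the NRF2 and antioxidant list were lower, 4 of 14, or 8 adjusted over the list alone (camera adjusted p = 1.50e-06, adjusted p = 0.285 with an estimated correlation). So were 2 of 21 NF-kB genes, 20 adjusted over the list alone (camera adjusted p = 1.65e-17, adjusted p = 0.285 with an estimated correlation). With flagellin the proliferation list had a median of 0.47, with 0 genes passing over all genes and 18 adjusted over the list alone (camera adjusted p = 1.07e-21, adjusted p = 0.160 with an estimated correlation). Markers of other cells moved with these lists. Neutrophil genes had medians of 0.65 unstimulated (camera adjusted p = 4.00e-06, adjusted p = 0.355 with an estimated correlation) and 0.82 with flagellin (camera adjusted p = 5.15e-11, adjusted p = 0.374 with an estimated correlation). Stromal genes had 1.06 (camera adjusted p = 1.88e-06, adjusted p = 0.355 with an estimated correlation) and 1.01 (camera adjusted p = 1.46e-09, adjusted p = 0.374 with an estimated correlation). Of the 13 neutrophil genes 1 and 0 passed, 5 and 12 adjusted over the list alone, and of the 14 stromal genes 0 and 0, with 8 and 3.

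In total 183 genes differed between CB-R1 and C3Bir on the arrays labelled unstimulated, 142 higher and 41 lower in CB-R1, and 10 on those labelled flagellin. The first count was 1766, 6 and 6 without C3Bir unstimulated array 1, 2 or 3 and 6, 7 and 414 without CB-R1 unstimulated array 1, 2 or 3. It was 8 in a fit of the 6 arrays alone, 288 without genes of low values, 407 with the replicate number as a block, 3 without the 4 high arrays and 2731 without the 3 arrays apart. Only Gbp2b, Ifi44l, Mcoln3 and Olfml3 of the 35 genes selected for naming passed whichever array was left out. The second was 74 and 5 without C3Bir flagellin array 1 or 3, 5 without CB-R1 flagellin array 1. It was 17 over all probe sets, 61 in a fit of the 6 arrays alone, 21 with the replicate number as a block and 111 without the 3 arrays apart. Those 4 genes and Ppbp passed whichever array was left out.

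The Cdcs1 allele effect, the mean difference between the C3Bir and the B6 form of the region over both backgrounds and conditions, averages comparisons that can differ from each other. With the C3Bir form Ifi44l was higher by 4.81 ± 0.17, Gbp2b by 4.12 ± 0.28, S1pr1, a sphingosine phosphate receptor, by 0.84 ± 0.12 and Miga1, of mitochondrial fusion, by 0.71 ± 0.08 (log2 ± SE over 24 arrays). Olfml3 stood at -2.53 ± 0.10, Chil3 at -1.20 ± 0.12 and Mcoln3 at -1.18 ± 0.06. Between the parents Chil3 stood at -0.37, C3Bir against B6, on the arrays labelled flagellin (adjusted p 0.434), and its mean lay above both parents in CB-R1 and below both in BC-R3. These 7 genes lie on chromosome 3 and had adjusted p values of at most 8.39e-04; Gbp2b, S1pr1, Olfml3 and Chil3 have 1 probe set each. Off chromosome 3, the nuclear RNA Malat1 was higher by 0.62 ± 0.11. Chromosome 3 held 36 of 235 changed genes with a position and 913 of the 18021 tested, an odds ratio of 3.49 (Fisher's exact test, two-sided, adjusted p 5.45e-08 over 20 chromosomes). Within the order of those 913 genes, 30 of the 36 lay between positions 575 and 909. In the list of genes near Cdcs1 3 of 38 were higher and 2 lower, with 6 lower and 8 higher adjusted over the list alone (camera adjusted p = 0.502, adjusted p = 0.678 with an estimated correlation). Interferon-stimulated genes were lower with the C3Bir form in 2 of 30, 22 adjusted over the list alone (camera adjusted p = 1.34e-13, adjusted p = 0.493 with an estimated correlation). Stromal markers were lower in 2 of 14, 14 adjusted over the list alone (camera adjusted p = 1.76e-12, adjusted p = 0.493 with an estimated correlation). Proliferation genes were lower in 1 of 23, 8 adjusted over the list alone (camera adjusted p = 1.06e-06, adjusted p = 0.493 with an estimated correlation). The backgrounds went opposite ways in this list: for BC-R3 against B6 on the arrays labelled unstimulated 9 genes were higher and 2 lower with the C3Bir form, with 2 lower and 9 higher adjusted over the list alone (camera adjusted p = 0.00263, adjusted p = 0.576 with an estimated correlation), while CB-R1, with the B6 form, also lay higher than C3Bir. The median differences of BC-R3 against B6 unstimulated and with flagellin were 0.32 and 0.16 for proliferation, -1.61 and 0.18 for interferon-stimulated genes and -0.99 and 0.21 for stromal markers. Those of CB-R1 against C3Bir were 0.56 and 0.47, 0.04 and 0.54, and 1.06 and 1.01.

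In total 236 genes differed by allele, 129 higher and 107 lower with the C3Bir form, and 7 at least 2-fold. Without B6 unstimulated array 1, 2 or 3 the count was 1183, 57 and 49, without B6 flagellin array 1 487. Without C3Bir unstimulated array 1, 2 or 3 it was 434, 92 and 70, and without C3Bir flagellin array 1, 2 or 3 430, 145 and 42. Without BC-R3 unstimulated array 1, 2 or 3 it was 749, 69 and 76, without BC-R3 flagellin array 1 or 3 91 and 76. Without CB-R1 unstimulated array 1 or 2 it was 86 and 114, and without CB-R1 flagellin array 1, 2 or 3 66, 106 and 129. It was 424 over all probe sets, 104 with same-numbered arrays as a random block, 15 without the 4 high arrays and 2204 without the 3 arrays apart. Of the 26 genes selected for naming 9 passed whichever array was left out, the 7 named genes of chromosome 3, Malat1 and Dusp1.

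**Figure D3:**
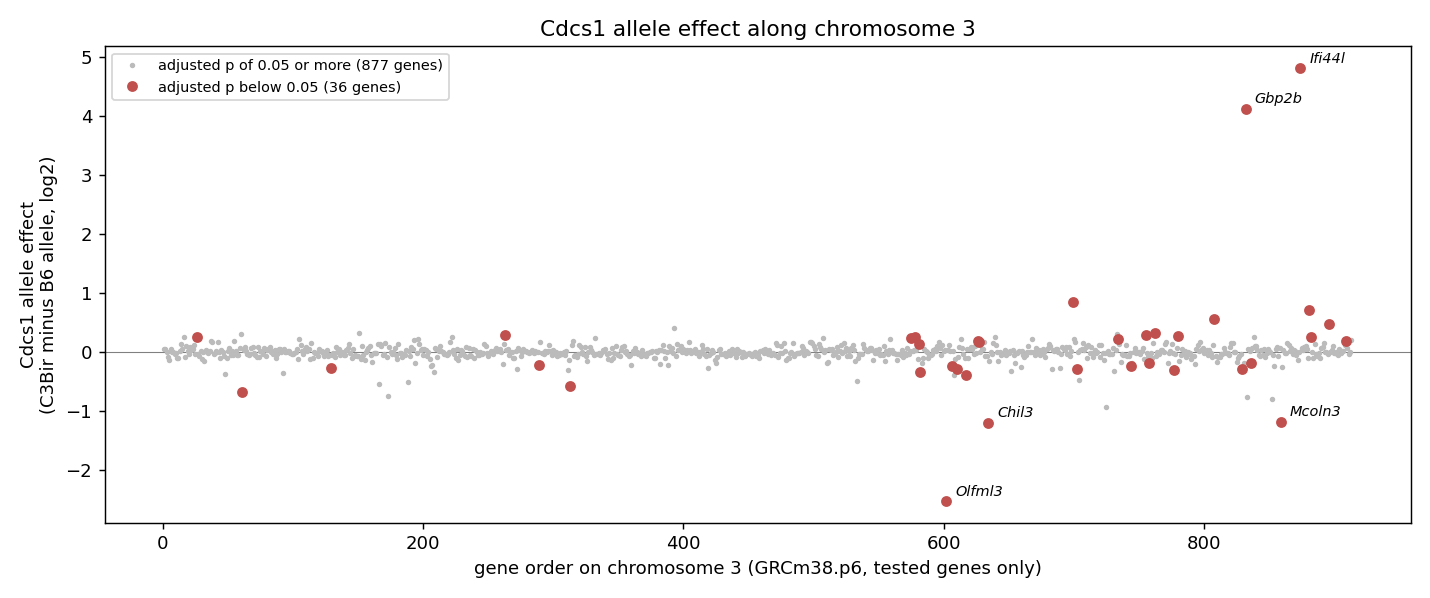
Cdcs1 allele effect (y axis, log2 difference, C3Bir minus B6 form) of the 913 tested genes of chromosome 3 in their order on GRCm38.p6 (x axis, tested genes only), with the 36 genes that passed limma's test as large points. Of these, 30 lie between positions 575 and 909, with Ifi44l at 4.81, Gbp2b at 4.12 and Olfml3 at -2.53.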

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

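The tests of exchanged arrays, of another cell type and of a run by replicate number were chosen after the results they bear on had been seen; those of probe sets, of the leading component and of other splits were not. By the test of the difference itself, 1917 genes differed between BC-R3 and B6 in their change with flagellin, 757 with a higher and 1160 with a lower change in BC-R3.

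In B6 inflammatory genes were lower on the arrays labelled flagellin, and the share of B6 and of BC-R3 in the difference was not tested. An exchange of arrays between strains is argued against, since 12 of the 12 arrays labelled unstimulated matched their own strain on genes chosen in the flagellin arrays. An exchange of condition labels across a whole strain cannot be told apart from a true fall in B6, where 3 of 3 arrays labelled unstimulated lay above all 3 labelled flagellin on the cytokine mean, or in C3Bir, where 2 of 3 did and the remaining one, at 7.56, lay below the lowest of them, 7.62, by less than their range. Another cell type in the B6 unstimulated arrays could not be excluded either: the lowest median of the marker lists was -0.743, for stromal genes, with 0 of 14 lower by limma's test, while B6 flagellin array 2 had a stromal mean of 9.17, above the 9.05 of B6 unstimulated array 2. Strain, condition and activation before harvest remain open as biological explanations, untested here.

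In 3 of the groups labelled unstimulated, array 1 stood apart from arrays 2 and 3, with mean correlations of 0.988, 0.990 and 0.989 in B6, C3Bir and BC-R3 against 0.997, 0.998 and 0.998 between the other two. A run that follows the replicate number cannot be told apart from other causes: deviations of same-numbered arrays of different strains correlated at 0.0333 over genes on average, but from -0.508 to 0.553 between single pairs, and the array apart had number 1 in these 3 groups but not in every group, with B6 flagellin array 2 at 0.989 against 0.994 and CB-R1 unstimulated array 3 at 0.994 against 0.998. Unstimulated array 1 had the lowest cytokine mean in B6 and C3Bir (8.12 and 7.56) and the highest in BC-R3 (8.12). The first component of the residuals held 33.0% of their variance. On it the mean absolute loading of the cytokine list exceeded that of 100% of 10000 random lists, and so did those of the interferon-stimulated and chemokine lists. The random lists were matched on mean level but not on spread or correlation, so lists of widely varying genes can load high whatever the cause. A difference in activation among cultures of one label stays possible, but this test cannot single it out. What led to such a difference, a plate, a donor or a contaminant of the medium, was not tested.

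The genes of chromosome 3 that differed by Cdcs1 allele could reflect sequence variants under the probes rather than expression. Of 36 genes 22 had another probe set, and in 17 of these at least 1 other probe set went the same way at an unadjusted p under 0.05, Ifi44l and Mcoln3 among them. How often this occurs without a difference was not computed. In 4 another probe set had the opposite sign, in 2 of them at an unadjusted p under 0.05. Of these 4, Camk2d and Pdlim5 are also among the 17. For those of the 17 with no probe set of opposite sign, the values argue against variants under the chosen probe set alone as the whole cause. Variants under more than 1 probe set of a gene were not examined and stay possible. For the 14 genes with 1 probe set, including Gbp2b, Olfml3, Chil3 and S1pr1, variants and expression cannot be told apart. Regulation by the locus stays a hypothesis.

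Other splits of the same arrays were fitted for each count of genes. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The B6 flagellin contrast gave 4068 genes and the highest other split 2536, with 1 of 10 as large. The flagellin contrasts in C3Bir, BC-R3 and CB-R1 gave 0, with 0, 4 and 1 as the highest other; 10 of 10 splits were as large, as any split must be against a count of 0. C3Bir against B6 gave 3046 against 384 unstimulated and 1207 against 14 with flagellin, BC-R3 against B6 5513 against 3395 and 3 against 2, and CB-R1 against C3Bir 183 against 0 and 10 against 0, each with 1 of 10 as large.

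For the Cdcs1 allele effect 3 of 100 splits, the real one among them, gave as many as 236 genes, and the others gave 1999 and 1624. The share is low, but regrouped arrays gave more genes than the real labels, so chance is not excluded. For the difference between BC-R3 and B6 3 of 100 splits, the real one among them, gave as many as 1917, and the others gave 2566 and 2240. The split with 2566 kept 2 of 6 labels in each strain. Chance is not excluded here either. Such splits were made for 16 counts, and the shares are not adjusted for that number. For the differences by C3Bir against B6, CB-R1 against C3Bir, background and allele the real count was 0, against which all 100 of 100 splits are as large whatever they give, so they say nothing about chance; the highest others were 3378, 2, 3132 and 3. The split with 3378 genes reversed all labels of C3Bir and kept those of B6, which adds the labelled changes of both strains, and that with 1999 kept all labels of BC-R3 and B6 unstimulated, so labelled differences can give such counts and a further structure was not tested.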

How the results depend on the processing

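The exclusions of 4 and of 3 arrays were chosen after seeing the data. Results are given in the order of the report. The alternatives that kept most counts within 1.5 times were quantile normalization (largest shift of a median gene 0.0122 log2), median centring (0.0407), trend and robust eBayes, the low-value filter, all probe sets, the mean of probe sets and the 3 replicate blocks; the medians of all 142 called list tests kept their sign under both scalings. Exceptions were 1125 genes for the difference BC-R3 against B6 after quantile normalization, 288 for CB-R1 against C3Bir unstimulated with the filter, and over all probe sets 5 for BC-R3 against B6 with flagellin, 17 for CB-R1 against C3Bir with flagellin and 424 for the allele effect. The mean of probe sets gave 6 genes for the BC-R3 flagellin contrast. Median centring moved the balance of directions, to 2921 higher and 1196 lower with flagellin in B6, 517 higher and 619 lower for C3Bir against B6 with flagellin and 587 higher and 1533 lower for the difference BC-R3 against B6, and quantile normalization gave 615 higher and 510 lower for that difference and 9 higher and 5 lower for CB-R1 against C3Bir with flagellin. The cause was not tested in any of these. The number of arrays limits precision throughout, and as the values are already log2 no offset was added.

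The replicate numbers are not known to pair arrays: deviations of same-numbered unstimulated and flagellin arrays of a strain correlated above 0.1 in 8 of 12 pairs, from -0.536 to 0.505. In C3Bir the 3 pairs gave 0.307 to 0.484 and in CB-R1 0.299 to 0.505, each the best match of its unstimulated array. In B6 they ranged from -0.349 to 0.110 and in BC-R3 from -0.536 to 0.313. With a replicate block the B6 flagellin count was 4741 for a random donor (correlation 0.0916), 4348 for a paired, fixed donor and 4200 for the number over all strains, and the random donor gave 144 called list tests. The random donor gave 14 genes in the BC-R3 flagellin contrast and 104 for the allele effect, and the number over all strains gave 407 and 21 for CB-R1 against C3Bir unstimulated and with flagellin. Which block is right could not be settled from the labels.

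A fit of the compared arrays alone has fewer arrays to estimate the spread and takes it only from the compared groups. It gave 0 genes for the B6 flagellin contrast, 1104 and 665 for C3Bir against B6 and 7 for BC-R3 against B6 unstimulated. For CB-R1 against C3Bir it gave 8 and 61, the latter above the 10 of the main fit, and 0 for the difference BC-R3 against B6. The main fit shares 1 spread per gene over groups that vary unequally. Its p-values can thus be too small for contrasts with a widely varying group, such as B6 unstimulated. A 2-fold threshold gave 302, 377, 175, 502, 31, 6, 7 and 289 for the B6 flagellin contrast, C3Bir against B6 in both conditions, BC-R3 against B6 unstimulated, CB-R1 against C3Bir in both conditions, the allele effect and the difference BC-R3 against B6. With the 4 high arrays aside, which leaves B6 and C3Bir unstimulated with 1 array each, assumed to vary like the other groups, the counts were 0 for the B6 flagellin contrast, 255 for C3Bir against B6 unstimulated, 3 for BC-R3 against B6 unstimulated, 3 for CB-R1 against C3Bir unstimulated, 15 for the allele effect and 0 for the difference BC-R3 against B6. With unstimulated array 1 of B6, C3Bir and BC-R3 aside they were 6282, 1234 and 905 for the flagellin contrasts of these strains, 2030 for C3Bir against B6 with flagellin, 2731 and 111 for CB-R1 against C3Bir, 2204 for the allele effect, and 1495, 5669, 810, 379 and 1006 for the 5 differences. Leaving out arrays that lie far from their group lowers the estimated spread, so these rises follow in part from the choice.

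Leaving out each array in turn gave 985 to 5645 genes for the B6 flagellin contrast, 0 to 93, 0 to 213 and 0 to 0 for those of C3Bir, BC-R3 and CB-R1, 1582 to 4203 and 785 to 1317 for C3Bir against B6 unstimulated and with flagellin, 2757 to 6606 and 3 to 4 for BC-R3 against B6, 6 to 1766 and 5 to 74 for CB-R1 against C3Bir and 42 to 1183 for the allele effect. For the differences C3Bir against B6, BC-R3 against B6, CB-R1 against C3Bir, by background and by allele it gave 0 to 1373, 40 to 4231, 0 to 4, 0 to 270 and 0 to 217. Of the 142 called list tests 0 were called with an estimated correlation, with 17 at an unadjusted p under 0.05. Over all list tests, and not only these 142, fry called 34, but it tests another question. The 755 values of genes selected for naming had 15965 alternatives, and 482 of the values were called in the main fit. Of the alternatives 13324 counted as kept, which for called values means direction and side of the threshold. A value not called counted as kept wherever it stayed uncalled, whatever its direction. A further 2482 kept only the direction, 153 newly passed, and 6 changed sign with a call before or after. These were Fosb, Csf1 and Ifnb1 in the B6 flagellin contrast with the 4 high arrays aside (0.009, 0.002 and 0.003 log2, against -0.56, -1.02 and -0.37), and with the mean of probe sets Pdxdc1 and Ctsl for C3Bir against B6 with flagellin (-0.105 and -0.428, against 2.60 and 0.44) and Camk2d for the allele effect (-0.006, against 0.29). The cause was not tested for these 6.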

Other observations

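Neutrophil granule genes were abundant on every array of these macrophage cultures. The mean log2 value over 13 neutrophil markers was 11.17 to 11.44 in CB-R1, 10.21 to 11.11 in C3Bir, 9.75 to 10.54 in BC-R3 and 9.77 to 10.60 in B6, so the 6 arrays of CB-R1 lay above the other 18. The proliferation list ran the same way, at 8.59 to 8.78 in CB-R1 against 7.69 to 8.40 on the other 18 arrays. The stromal list ranged more widely within a strain, from 7.33 to 9.57 in B6 and 8.54 to 9.17 in CB-R1.

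Over all 18193 genes 1726 were lower and 2342 higher with flagellin in B6, and markers of 6 other cell types are set beside these counts. B cell markers had 1 of 11 lower and 0 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.242, adjusted p = 0.640 with an estimated correlation), T and NK cell markers 3 of 11 lower and 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.313, adjusted p = 0.640 with an estimated correlation) and dendritic cell markers 1 of 9 lower and 0 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.119, adjusted p = 0.640 with an estimated correlation). Eosinophil markers had 1 of 6 lower and 0 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.549, adjusted p = 0.640 with an estimated correlation), osteoclast markers 1 of 10 lower and 0 higher (0 and 0 adjusted over the list alone, camera adjusted p = 0.733, adjusted p = 0.894 with an estimated correlation) and endothelial and adipocyte markers 2 of 8 lower and 0 higher (3 and 1 adjusted over the list alone, camera adjusted p = 0.408, adjusted p = 0.640 with an estimated correlation). Immediate early genes had 2 of 18 lower and 2 higher (3 and 2 adjusted over the list alone, camera adjusted p = 0.698, adjusted p = 0.768 with an estimated correlation), with Jun, a subunit of the factor AP-1, at 0.67 ± 0.14. Genes of alternative activation had 1 of 14 lower and 0 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.698, adjusted p = 0.881 with an estimated correlation). Genes near Cdcs1 had 6 of 38 lower and 8 higher (7 and 8 adjusted over the list alone, camera adjusted p = 0.886, adjusted p = 0.905 with an estimated correlation), with Manba, lysosomal beta-mannosidase, at 0.83 ± 0.16.

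The reciprocal congenic comparisons share no arrays, so their overlap can be counted. With flagellin Ifi44l and Gbp2b were called higher and Olfml3 lower with the C3Bir form in both, where 2.20e-04 and 4.40e-04 shared genes would be expected if calls were independent. On the arrays labelled unstimulated 4 genes were shared as higher and 8 as lower, below the 7.20 and 18.1 expected, and 58 were called in opposite directions against 30.2 expected. Genes are not independent, and no test was made of these overlaps.

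The share of called genes was compared with the share of tested genes on each of 20 chromosomes by Fisher's exact test, two-sided. Chromosome 3 held 3 of the 3 genes of BC-R3 against B6 with flagellin (adjusted p 0.00259). It held 20 of 182 for CB-R1 against C3Bir unstimulated (odds ratio 2.34, adjusted p 0.0203) and 6 of 10 with flagellin (odds ratio 28.2, adjusted p 5.86e-05). For BC-R3 against B6 unstimulated chromosome 7 held fewer than its share, 374 genes (odds ratio 0.812, adjusted p 0.0164).

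The change with flagellin over 18193 genes correlated at 0.593 between B6 and C3Bir and at 0.419 between BC-R3 and CB-R1. The other 4 pairs of strains gave -0.283, -0.284, -0.274 and -0.262. These 6 correlations are across genes, which are not independent replicates, and carry no test.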
